A study of Mus musculus with 12 samples.

How the data were processed

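RNA was measured in 12 mouse skin libraries in 3 labelled groups: 3 wild-type control libraries, 5 libraries of the imiquimod (IMQ) group and 4 libraries of the group that was both IMQ-induced and deficient for Tcn2 (Tcn2-/- IMQ). Per the labels' protocols, libraries were made from total RNA by oligo(dT) capture of polyadenylated RNA, fragmentation, random-hexamer priming, bead size selection and PCR, so 3' ends and degraded RNA can be captured unevenly and PCR copies of a molecule cannot be told apart. The deposited values are whole-number counts per gene, not normalized, and per the submitters' processing notes the genome build was GRCm39. The aligner, the counting program, the annotation release and whether counting used strand are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical family members can therefore be assigned to the wrong gene, and such genes are named as uncertain. Coordinates are those of the deposited count table. Groups and replicate numbers came from the sample titles, and 0 columns of per-sample values were left unmapped. The titles also carry the word muscle while the tissue and source labels give skin.

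The table held 33539 genes, of which 201 had no symbol and 821 had no count in any library. Total counts per library ranged from 16182324 to 18503487, and values below 1 CPM, the count scaled to library size, rest on few reads. Counts were analysed in R 4.3.3 with edgeR 4.0.16. The filter filterByExpr, applied over the 3 groups, kept 18147 genes. Library sizes were scaled with TMM factors (0.927 to 1.11). One quasi-likelihood model (glmQLFit and glmQLFTest, 2-sided) was fitted to all 12 libraries with a mean per group, so the 3 groups share 1 estimate of the spread, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called changed at an adjusted p below 0.05. The common biological coefficient of variation was 0.463. Values per library are CPM with TMM factors. Group values are the mean ± SD of CPM. Log2 CPM used for principal components and list scores had a prior count of 2. Changes are given on the log2 scale with the standard error (SE).

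Gene lists for psoriasis-like skin, for vitamin B12 handling and for the cell types a skin sample can hold were written down with the tests, the named genes and most of the other settings tried before the data were examined. Of 774 listed genes 767 were found, in 32 lists with at least 5 measured members each. Lists were tested with camera (limma 3.58.1) at the preset correlation between genes of 0.01, adjusted over the 32 lists, and again with a correlation estimated from the residuals and with fry. Camera compares a list with all other genes, and fry asks whether the genes of a list move one way on balance. Counts of changed members are given over all genes and adjusted over the list alone. The genes named were chosen from Tcn2, a fixed set of 20 readouts, the 5 genes per comparison and direction with the largest change among called genes (at least 1 CPM in the higher group, no overlap between the groups' libraries and a symbol that is not a gene model), up to 4 called members of each list or the 2 with the smallest p where none was called, and genes a check points to. Genes named outside this rule are said to be so. Not every gene that the rule picks is reported here. Where a group held no count of a gene, the fold was computed against a floor of 3 counts over the group, and where it held 1 to 3 counts, a ratio of counts per total counts is given with its exact 95% counting interval. Such intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

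The other settings chosen in advance were DESeq2 1.42.0, RLE and upper-quartile factors, no filter on low counts, a filter of at least 1 CPM in 3 libraries, a fit of only the groups compared, limma voom with sample quality weights, the replicate number as a block, a skeletal muscle or hair follicle score as a covariate, and leaving out each library in turn. After the data were seen, 4 more were added: sex as a covariate, only the 9 libraries with Y-linked reads, and leaving out the 2 or the 3 libraries lowest on the first principal component. Other splits of the libraries, simulated libraries with no effect and exact or resampled permutation tests served as further checks. The fits were tested on simulated counts with 200 of the genes changed by known folds. For IMQ against control, 10% of genes changed 2-fold were recovered, 56% of those changed 4-fold, 70% of those changed 8-fold and 84% of those changed 16-fold. The same shares were 12%, 58%, 78% and 90% for Tcn2-/- IMQ against IMQ, and 4%, 48%, 72% and 72% for Tcn2-/- IMQ against control. The unchanged genes called in these tests numbered 5, 6 and 3. The simulated counts were drawn independently for each gene and library. Differences that many genes of a library share, such as those on the first principal component, were not in them. The recovered shares may therefore be too high for the real samples. No sample was left out.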

Results

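Imiquimod (IMQ), an agonist of Toll-like receptors, gives a psoriasis-like inflammation when applied to mouse skin. Tcn2 encodes transcobalamin, the carrier that delivers vitamin B12 from plasma to cells. Polyadenylated RNA of mouse skin was sequenced in 12 libraries: 3 from wild-type control skin, 5 from IMQ-induced skin and 4 from IMQ-induced skin of Tcn2-deficient animals (Tcn2-/- IMQ). Library totals were 16325012, 16700296 and 16980929 counts in the controls. They were 16640433 to 17461680 counts in the IMQ group and 16182324 to 18503487 counts in the Tcn2-/- IMQ group. Between 21417 and 24411 genes had a count in each library. Mitochondrially encoded genes took 2.78% to 10.3% of the counts, with the highest shares in control replicate 1 (10.3%) and Tcn2-/- IMQ replicate 2 (8.08%). These same libraries lay lowest on the first principal component, which held 34.1% of the variance, at −140.5 and −98.6. The other controls lay at −24.9 and −17.8, and Tcn2-/- IMQ replicates 3 and 4 at 52.6 and 44.5. Xist, transcribed from the inactive X chromosome of females, had 26187, 24187 and 18572 counts in control replicates 2 and 3 and IMQ replicate 1. The other 9 libraries had 1605 to 2699 counts of the Y-linked gene Ddx3y. The titles carry the word muscle beside the skin label, and skeletal muscle genes were present in every library. The mean log2 CPM of 29 muscle genes was 8.05 to 8.18 in the controls, 5.99 to 7.44 in the IMQ group and 7.58 to 9.71 in the Tcn2-/- IMQ group. The labels do not say whether replicates came from separate animals. The sex counts show only that control replicate 1 and IMQ replicate 1 came from other animals than the rest of their groups. The p-values measure only the spread between these samples, part of which may be technical.

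Tcn2 transcripts were low in every library labelled Tcn2-/-. Tcn2 (ENSMUSG00000020432, chromosome 11, 3867192 to 3882159, minus strand, GRCm39) stood at 19.9, 75.9 and 85.9 CPM in the controls and at 90.3, 67.0, 137, 130 and 141 CPM in the IMQ libraries. In the Tcn2-/- IMQ libraries it stood at 5.59, 1.91, 5.44 and 4.14 CPM. Tcn2 fell from 113 ± 32.6 CPM (SD, n = 5) in IMQ skin to 4.27 ± 1.7 CPM (n = 4) in Tcn2-/- IMQ skin. This is a log2 change of −4.72 (SE 0.505, adjusted p = 0.00695, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The change against control was −3.83 (SE 0.506, adjusted p = 0.00789), and between IMQ and control skin Tcn2 differed by 0.90 (SE 0.463, adjusted p = 0.376). Cd320, which encodes the cell surface receptor for transcobalamin-bound vitamin B12, stood at 17.6 ± 0.87, 14.6 ± 4.53 and 13.0 ± 2.99 CPM in control, IMQ and Tcn2-/- IMQ skin. The Tcn2 difference between Tcn2-/- IMQ and IMQ skin had an adjusted p of 1.12e-22 to 0.197 over all settings. This difference missed the threshold without Tcn2-/- IMQ replicate 1 (−4.88, adjusted p = 0.0502) or 4 (−4.71, adjusted p = 0.0776). With the muscle score as a covariate (−5.07, adjusted p = 0.109) or the replicate number as a block (−4.60, adjusted p = 0.197) it also missed the threshold. The difference from control missed it without control replicate 3 (−3.49, adjusted p = 0.0608), with sex as a covariate (−3.19, adjusted p = 0.1) and among libraries with Y-linked reads, which hold 1 control (−2.27, adjusted p = 0.218), where the lowest was 2.26e-11.

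**Figure D1:**
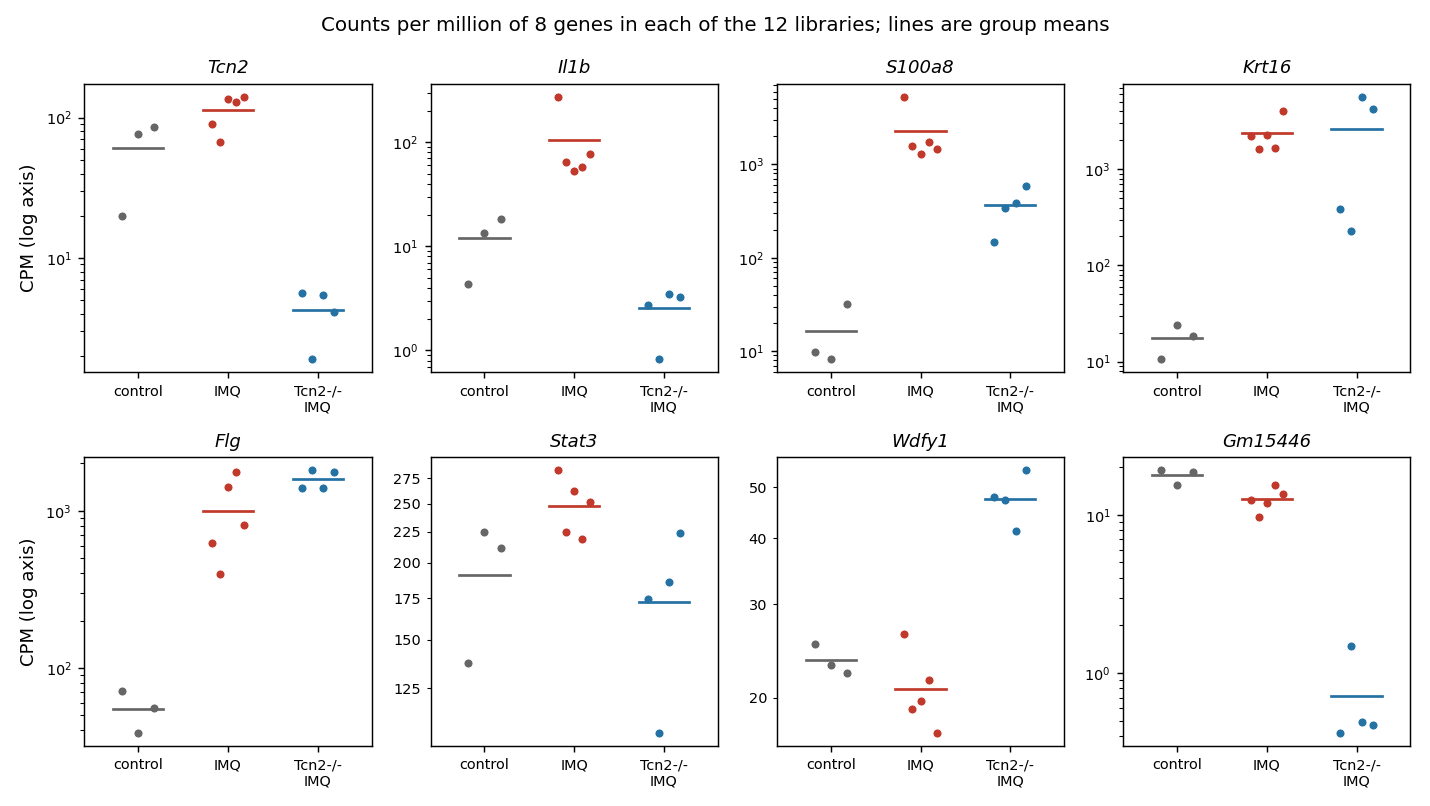
CPM on a log axis for Tcn2, Il1b, S100a8, Krt16, Flg, Stat3, Wdfy1 and Gm15446 in control, IMQ and Tcn2-/- IMQ skin, where each point is a library and each line a group mean. Tcn2 lies at 1.91 to 5.59 CPM in the Tcn2-/- IMQ libraries, and Il1b lies at 0.83 to 3.52 CPM there.

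The first comparison asked how the skin of the IMQ psoriasis model differed from wild-type control skin. The lists of wound-type epidermal genes, cornification genes and antimicrobial proteins were higher in IMQ skin at the preset correlation, but missed the threshold with an estimated one (adjusted p = 0.0874, 0.35 and 0.273). Krt16, a keratin of hyperproliferative epidermis, rose from 17.8 ± 6.79 CPM (SD, n = 3) to 2354 ± 983 CPM (n = 5), a log2 change of 7.05 (SE 1.2, adjusted p = 0.0223, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). S100a8, a calprotectin subunit made by neutrophils and activated keratinocytes, rose from 16.6 ± 13.2 to 2277 ± 1690 CPM (7.10, SE 0.866, adjusted p = 0.00568). Flg, which encodes the filaggrin precursor of the cornified layer, rose from 55.0 ± 16.3 to 999.7 ± 566 CPM (4.18, SE 0.521, adjusted p = 0.00568). Krt77, a keratin of differentiated epidermis and sweat ducts, fell from 952 ± 577 to 6.59 ± 7.14 CPM (−7.17, SE 1.13, adjusted p = 0.0148).

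Of 35 measured stress keratin and wound-type epidermal genes 24 rose and 11 did not pass (32 rose when adjusted over the list alone). Their median log2 change was 6.51, or 6.18 with low-count members at their bounds. Among them Sprr2b, a precursor of the cornified envelope, rose by 10.20 (SE 1.34, adjusted p = 0.00666) and Krt6a by 4.89 (SE 1.01, adjusted p = 0.0422). Lce3a, a late cornified envelope gene, had 2 counts over the controls and 8775 over the IMQ libraries, a ratio of 2800 (95% counting interval 776 to 23200, adjusted p = 0.032). Of 44 epidermal differentiation genes 9 rose and 1 fell over all genes, and 28 rose and 3 fell when adjusted over the list alone. Rptn (7.43, adjusted p = 0.0348) and the transglutaminase Tgm3 (4.56, adjusted p = 0.0434) were among those that rose. Of 18 antimicrobial genes 4 rose (11 adjusted over the list alone), including the beta-defensins Defb3 (8.62, adjusted p = 0.0317) and Defb14 (4.69, adjusted p = 0.00862). S100a9, which encodes the partner of S100a8 in calprotectin, rose from 20.8 ± 14.9 to 2389 ± 2070 CPM (6.84, SE 1.07, adjusted p = 0.0148). The list tests at the preset correlation gave adjusted p = 6.75e-61, 1.12e-21 and 2.22e-12 for these 3 lists, and adjusted p = 0.0874, 0.35 and 0.273 with an estimated correlation. Other genes with the largest rises were the protease inhibitors Spink7 (2 counts against 6322, ratio 2020, interval 559 to 16700) and Serpinb3d (1 count against 1803, ratio 1150, interval 207 to 45500). Lce3b rose by 9.63 (SE 1.83, adjusted p = 0.0332) and Lce3e by 9.27 (SE 1.59, adjusted p = 0.0223). Members of the Lce3, Sprr2, Serpinb3, Krt6, Stfa, Klk1, beta-defensin and haemoglobin families share sequence, so the split of reads between copies is uncertain.

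The series title names Il1b, which encodes the inflammatory cytokine interleukin-1β, and Stat3, a transcription factor downstream of many cytokine receptors. Il1b (ENSMUSG00000027398, chromosome 2, 129206490 to 129213059) stood at 12.1 ± 7.17 CPM in control and 105 ± 94.6 CPM in IMQ skin (3.12, SE 0.729, adjusted p = 0.0635). Stat3 stood at 191 ± 47 and 248 ± 26.5 CPM (0.38, SE 0.243, adjusted p = 0.481). Socs3, a feedback inhibitor that STAT3 induces, stood at 26.5 ± 8.98 and 56.8 ± 19.6 CPM (1.10, adjusted p = 0.225). Il17f, a cytokine of type 17 lymphocytes, stood at 0.131 and 1.30 ± 0.401 CPM (3.24, adjusted p = 0.0827). Il17a had 0, 0 and 6 counts in the controls and 20, 3, 0, 1 and 27 in the IMQ libraries. Il22 had counts of 10 and 1 in 2 IMQ libraries, and Il23a had 0 to 8 counts in controls and 4 to 66 in IMQ libraries. These 3 cytokine genes were too low to test. The neutrophil-associated Lcn2 (4.12, adjusted p = 0.0599) and the neutrophil chemoattractants Cxcl1 (1.64, adjusted p = 0.404) and Cxcl2 (5.57, adjusted p = 0.0993) did not pass. Il6 (2.06, adjusted p = 0.45), Tnf (0.95, adjusted p = 0.517), the cornified envelope gene Lor (1.11, adjusted p = 0.488) and the proliferation marker Mki67 (0.12, adjusted p = 0.912) did not pass either. Il1bos, an antisense transcript that overlaps Il1b and whose reads may not be separable from it, fell from 12.8 ± 6.71 to 1.07 ± 0.758 CPM (−3.56, SE 0.681, adjusted p = 0.0348).

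Among the lists of immune cell types, neutrophil markers had the most members changed. Of 18 markers 3 rose (14 adjusted over the list alone), namely Stfa2 (7.60, adjusted p = 0.0065), the receptor Trem1 (6.53, adjusted p = 0.0429) and the chemokine receptor Cxcr2 (4.99, adjusted p = 0.0348). Stfa2 did not follow this list throughout. In Tcn2-/- IMQ against IMQ skin it was at −0.02, where the list median was −1.95, so its rise may not stand for neutrophils. The list median was 2.96 (adjusted p = 1.34e-13, and adjusted p = 0.35 with an estimated correlation). The IL-23/IL-17 list of 12 genes had a median of 0.16 (adjusted p = 0.22), and 4 rose and 2 fell when adjusted over the list alone. Of 22 IL-1 and IL-36 family genes 1 fell, the interleukin-18 receptor chain Il18r1 (−2.04, SE 0.351, adjusted p = 0.0223), and 7 rose and 2 fell when adjusted over the list alone. The median of that list was 0.89 (adjusted p = 5.05e-05, and adjusted p = 0.487 with an estimated correlation). All 30 measured type I interferon response genes had negative changes (median −1.23, adjusted p = 2.6e-10, and adjusted p = 0.487 with an estimated correlation). Their list did not pass among libraries with Y-linked reads, where control replicate 1 is the only control (0.343). Irf9 at −1.09 (adjusted p = 0.142) and Stat2 at −1.19 (adjusted p = 0.252), which transmit interferon signals, did not pass singly.

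Further immune lists passed upwards with medians below that of the neutrophil list. These were JAK-STAT3 signalling (28 genes, median 0.43, adjusted p = 0.00019), TNF response (19 genes, 0.14, adjusted p = 0.0373), macrophages and monocytes (22 genes, 0.94, adjusted p = 4.5e-05), B cells (10 genes, 1.55, adjusted p = 0.00276) and mast cells (13 genes, 0.95, adjusted p = 0.00078). T cell markers passed downwards (25 genes, −1.17, adjusted p = 0.00276). With an estimated correlation these 6 gave adjusted p = 0.5, 0.616, 0.509, 0.419, 0.5 and 0.534. Adjusted over the list alone, 1 gene rose in each of the JAK-STAT3, TNF and mast cell lists. Among single members the osteopontin gene Spp1 was at 1.89 (adjusted p = 0.181), the high-affinity IgE receptor chain Fcer1a at 3.12 (adjusted p = 0.109) and the T cell receptor component Cd3e at −1.51 (adjusted p = 0.235). Chemokines (29 genes, 4 rose and 4 fell when adjusted over the list alone, adjusted p = 0.966), dendritic and Langerhans cell markers (20 genes, −0.50, adjusted p = 0.238) and type 2 cytokine genes (13 genes, adjusted p = 0.519) did not pass. The macrophage and mast cell calls were lost without control replicate 1 (adjusted p = 0.108 and 0.259). The TNF call was lost without control replicate 1 (0.693) or IMQ replicate 1 (0.0973) and the T cell call without control replicate 2 (0.175) or 3 (0.0685), or with sex as a covariate (0.233). Among libraries with Y-linked reads the T cell list passed in the other direction (upwards, 0.0413), against control replicate 1 as the only control. With the muscle score as a covariate the IL-1 and IL-36, JAK-STAT3, TNF and T cell calls ended (0.125, 0.125, 0.796 and 0.458). The score itself separates control from IMQ skin, so this fit cannot tell muscle content from the group difference.

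Lists of other tissue compartments also separated the groups. Of 29 skeletal muscle genes 28 had negative changes (median −1.18, 12 fell when adjusted over the list alone, adjusted p = 6.44e-12), for instance the troponin Tnni2 at −1.63 (adjusted p = 0.0755). Of 19 sebaceous gland genes 1 fell (6 adjusted over the list alone, median −1.74, adjusted p = 6.45e-10), the acyl-CoA synthetase Acsbg1 (−1.74, SE 0.335, adjusted p = 0.035). Of 25 matrix metalloproteinase and wound matrix genes (median 1.62, adjusted p = 2.6e-10) 1 rose, the aggrecanase Adamts4 (2.72, SE 0.504, adjusted p = 0.0316). Adjusted over the list alone 12 of them rose and 1 fell. Erythrocyte genes (8 genes, median 3, 6 rose when adjusted over the list alone, adjusted p = 6.79e-06), endothelial genes (16 genes, 1.06, adjusted p = 8.02e-07) and fibroblast genes (24 genes, 0.95, adjusted p = 6.65e-05) passed upwards. Barrier lipid genes (26 genes, 0.64, 9 rose and 1 fell when adjusted over the list alone, adjusted p = 0.00894), hypoxia and glycolysis genes (27 genes, 0.61, adjusted p = 0.00191) and hair shaft genes (36 genes, 3.65, adjusted p = 0.0373) passed upwards as well. In the hair list the hair keratin Krt84 rose by 6.45 (SE 1.34, adjusted p = 0.0422). The joint list of Schwann cell and melanocyte genes (15 genes, −1.23, adjusted p = 0.048) and mitochondrially encoded genes (13 genes, −0.68, adjusted p = 0.0237) passed downwards. With an estimated correlation the muscle, sebaceous, wound matrix and erythrocyte lists gave adjusted p = 0.35, and the endothelial list gave 0.487. The fibroblast, barrier lipid, hypoxia, and Schwann cell and melanocyte lists gave 0.534, the mitochondrial list 0.616 and the hair list 0.808. In the basal keratinocyte list Krt15, a keratin of the hair follicle bulge and basal layer, fell by 2.69 (SE 0.431, adjusted p = 0.0166), while the list did not pass (14 genes, adjusted p = 0.938). Cell cycle (45 genes, 0.12, adjusted p = 0.0736), vitamin B12 and one-carbon metabolism (38 genes, −0.11, adjusted p = 0.681), adipocyte (23 genes, 0.26, adjusted p = 0.519) and immediate early genes (20 genes, 0.19, adjusted p = 0.712) did not pass. Leaving out control replicate 1 ended the calls of the barrier lipid (adjusted p = 0.259), fibroblast (0.36), mitochondrial (0.962), and Schwann cell and melanocyte lists (0.995). Leaving out IMQ replicate 2 ended those of the barrier lipid (0.102), mitochondrial (0.156), Schwann cell and melanocyte (0.0981), and hair lists (0.78). The Schwann cell and melanocyte call was also lost without IMQ replicate 1 (0.177), and the hair call without control replicates 2 (0.334) or 3 (0.443) or IMQ replicate 5 (0.234). The muscle score as a covariate, which itself separates these groups, ended the barrier lipid (0.823), hypoxia (0.412), hair (0.125), mitochondrial (0.838), and Schwann cell and melanocyte calls (0.799).

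Over all genes 126 rose and 97 fell in IMQ skin, 223 of 18147 tested, of which 125 and 93 changed at least 2-fold. An unadjusted p below 0.05 was found for 2830. Besides Krt77, the largest falls were in the pseudogene Mrgprb11-ps (716 counts over the controls against 3, ratio 373, interval 127 to 1810) and the kallikrein Klk1b27 (314 against 3, ratio 164, interval 55.5 to 798). Hamp2, of the hepcidin family, had 82 counts over the controls and 0 over the IMQ libraries, at least 42.8-fold lower. Chat, which encodes choline acetyltransferase, had 68 and 0 counts, at least 35.5-fold lower. The libraries of both groups did not overlap for 1232 genes higher and 1343 genes lower in IMQ skin, where chance gives 324 each. With each of the 8 libraries left out in turn S100a8 kept its call (adjusted p 0.00522 to 0.0493). Flg lost it without control replicates 2 (0.0547) or 3 (0.0678), and S100a9 likewise (0.105 and 0.0732). Krt16 lost it without any 1 of the controls (0.0664, 0.117 and 0.135) or IMQ replicate 3 (0.0516) and Krt6a without each library but IMQ replicate 2 (up to 0.194). Of the 223 genes 99, 14 and 8 remained called without control replicates 1, 2 and 3 and 88, 210, 56, 78 and 58 without IMQ replicates 1 to 5. The count of all called genes was then 133, 15, 8, 92, 397, 56, 80 and 58. It was 1126 with DESeq2, 3028 with limma voom, 541 in a fit of these groups alone, 22 with the muscle score, 596 with the hair score and 143 with sex as a covariate. Among the libraries with Y-linked reads, which hold 1 control, it was 0 (edgeR, 4313 at an unadjusted p below 0.05). Of the 32 lists 23 passed with the preset correlation, 15 with the muscle score as a covariate, 0 with an estimated correlation (adjusted p from 0.0874) and 1 with fry (stress keratins, 0.0102). The median differed in sign from the mean for 2 lists and from the direction of the test for 3, the chemokine, basal keratinocyte and type 2 cytokine lists.

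**Figure D2:**
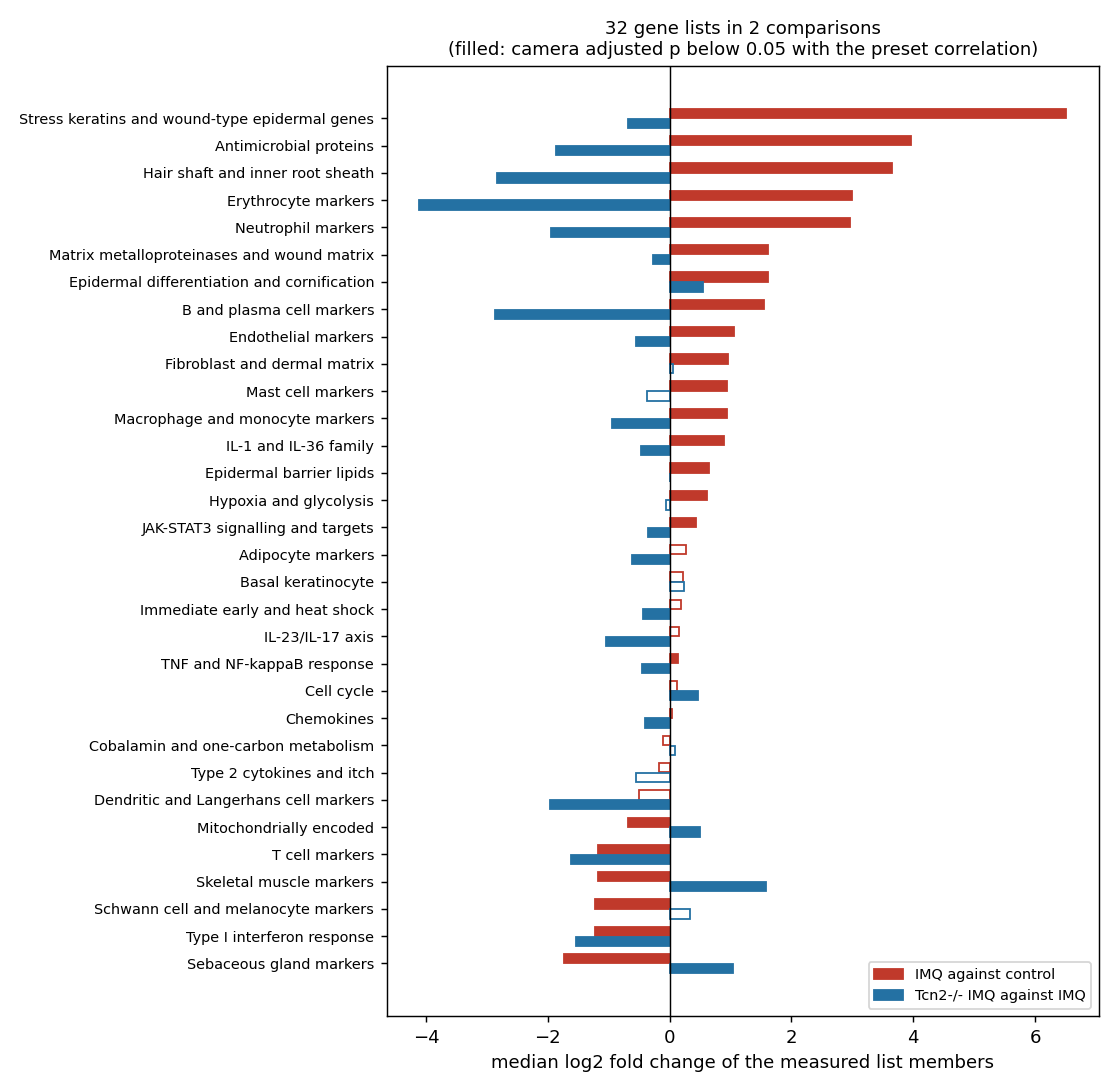
Median log2 change of the measured members of each of the 32 gene lists, in red for IMQ against control skin and in blue for Tcn2-/- IMQ against IMQ skin, where filled bars passed the list test with the preset correlation. The stress keratin list has the longest red bar at 6.51, and the erythrocyte list has the longest blue bar at −4.11.

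The central comparison asked how Tcn2-/- IMQ skin differed from IMQ skin. The labels give no Tcn2-/- group without IMQ. A genotype difference present before IMQ therefore cannot be told from a changed response to IMQ. Besides Tcn2, 4 genes passed. Il1b fell from 105 ± 94.6 CPM (SD, n = 5) in IMQ skin to 2.59 ± 1.22 CPM (n = 4) in Tcn2-/- IMQ skin. This is a log2 change of −5.34 (SE 0.73, adjusted p = 0.0349, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with all 4 Tcn2-/- IMQ libraries below all 5 IMQ libraries. Wdfy1 (chromosome 1, 79679979 to 79753860), which encodes an endosomal FYVE-domain protein, rose from 20.8 ± 3.5 to 47.6 ± 5.08 CPM (1.20, SE 0.155, adjusted p = 0.0247). The gene models Gm15446 (chromosome 5, 110071266 to 110091802) and Gm9733 (chromosome 3, 15361611 to 15397362), named here after their values were seen, fell. Gm15446 went from 12.6 ± 2.14 to 0.717 ± 0.516 CPM (−4.12, SE 0.397, adjusted p = 0.00457). Gm9733 went from 235 counts over the group to 2 (ratio 93.8, 95% counting interval 25.7 to 779, adjusted p = 0.0247).

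The other readouts did not pass over all genes. Stat3 stood at 248 ± 26.5 CPM in IMQ and 173 ± 49.3 CPM in Tcn2-/- IMQ skin (−0.52, SE 0.223, adjusted p = 0.385), and Socs3 at 56.8 ± 19.6 and 31.5 ± 14.6 CPM (−0.85, SE 0.366, adjusted p = 0.393). S100a8 stood at 2277 ± 1690 and 366 ± 182 CPM (−2.64, SE 0.605, adjusted p = 0.134), and S100a9 at 2389 ± 2070 and 356 ± 284 CPM (−2.75, adjusted p = 0.187). Tnf stood at 4.03 ± 3.58 and 0.617 ± 0.311 CPM (−2.70, adjusted p = 0.149). Lcn2 was at −2.32 (adjusted p = 0.262), Cxcl2 at −5.03 (adjusted p = 0.161), Cxcl1 at −0.79 (adjusted p = 0.717) and Il6 at 0.66 (adjusted p = 0.823). Il17f had 109 counts over the IMQ libraries and 3 over the Tcn2-/- IMQ libraries, a ratio of 29.0 (interval 9.67 to 143, adjusted p = 0.0983). Il17a had 1 count in 1 Tcn2-/- IMQ library, Il23a had 2 to 6 counts per library and Il22 had 0. Keratin readouts varied widely within the Tcn2-/- IMQ group. Krt16 averaged 2354 ± 983 and 2624 ± 2740 CPM, with 388, 230, 5666 and 4211 CPM in the 4 Tcn2-/- IMQ libraries, and Krt6a averaged 1937 ± 637 and 1734 ± 1820 CPM. Flg stood at 999.7 ± 566 and 1589 ± 230 CPM (0.67, adjusted p = 0.521) and Lor at 680 ± 374 and 1243 ± 450 CPM (0.87, adjusted p = 0.613). Mki67 stood at 217 ± 61.8 and 322 ± 145 CPM (0.57, adjusted p = 0.566), and Cd320 was at −0.18 (adjusted p = 0.8). Il1bos, the antisense transcript over Il1b, was at 1.07 and 1.08 CPM (0.01, adjusted p = 0.996).

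Markers of several leukocyte types were lower in Tcn2-/- IMQ skin as lists. Il1b was the only list member that passed over all genes, so the members below are counted as adjusted over the list alone. Of 20 dendritic and Langerhans cell markers 13 fell (median −1.97, adjusted p = 3.51e-16). They included the cytokine receptor Flt3 (−3.07, adjusted p = 0.0644 over all genes) and the antigen-presentation chaperone Cd74 (−3.40, adjusted p = 0.123). Of 18 neutrophil markers 10 fell (median −1.95, adjusted p = 9.76e-12), with the lectin receptor Clec4e at −4.78 (adjusted p = 0.117). Of 10 B cell markers 7 fell (median −2.87, adjusted p = 4.41e-08), with the immunoglobulin heavy chain gene Ighm at −3.04 (adjusted p = 0.125). Of 25 T cell markers 6 fell (median −1.62, adjusted p = 5.66e-12), among them the costimulatory receptor Icos (−2.99, SE 0.508, adjusted p = 0.0709). Of 22 macrophage and monocyte markers 4 fell (median −0.94, adjusted p = 4.79e-08). They were led by Ccr2, the receptor that recruits monocytes (−4.80, SE 0.801, adjusted p = 0.0709), and the monocyte antigen Ly6c2 (−5.75, adjusted p = 0.126). Macrophage scores were 4.90 and 2.98 in Tcn2-/- IMQ replicates 1 and 2, but 6.32 and 6.12 in replicates 3 and 4, near the IMQ libraries (6.40 to 7.40). All 8 erythrocyte genes fell (median −4.11, adjusted p = 4.75e-14), including Alas2 (−4.37, adjusted p = 0.122), the erythroid enzyme of haem synthesis. With an estimated correlation these 6 lists gave adjusted p = 0.117, 0.216, 0.117, 0.196, 0.326 and 0.117. Mast cell markers did not pass (13 genes, −0.36, adjusted p = 0.14).

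Cytokine lists passed downwards. These were IL-23/IL-17 (12 genes, median −1.05, 3 fell when adjusted over the list alone, adjusted p = 9.97e-06), IL-1 and IL-36 (22 genes, −0.46, 6 fell, adjusted p = 4.81e-08) and TNF response (19 genes, −0.46, 2 fell, adjusted p = 1.59e-07). Chemokines (29 genes, −0.41, 1 rose and 7 fell, adjusted p = 3.08e-05), antimicrobial proteins (18 genes, −1.87, 5 fell, adjusted p = 4.79e-08) and JAK-STAT3 signalling (28 genes, −0.36, adjusted p = 0.000373) also passed downwards. All 30 type I interferon genes were negative (median −1.53, adjusted p = 4.8e-09), and 31 of 35 stress keratin genes were negative (median −0.69, adjusted p = 2.07e-09). With an estimated correlation these 8 lists gave adjusted p = 0.174, 0.249, 0.249, 0.249, 0.196, 0.46, 0.46 and 0.326. Within them the T cell attractant Cxcl9 was at −3.85 (adjusted p = 0.128), the macrophage inflammatory protein gene Ccl3 at −4.92 (adjusted p = 0.123) and Irf9 at −0.99 (adjusted p = 0.253). The JAK-STAT3 call was lost without Tcn2-/- IMQ replicate 2 (adjusted p = 0.0686). Stress keratin scores were low only in Tcn2-/- IMQ replicates 1 and 2 (4.45 and 4.15), and replicates 3 and 4 (7.51 and 7.47) lay within the IMQ libraries (6.99 to 7.70). Interferon scores were 2.27 to 4.29 in Tcn2-/- IMQ skin, 6.65 in IMQ replicate 2 and 3.48 to 4.25 in the other IMQ libraries. Without IMQ replicate 2 the interferon gene Ifi44 went from −3.74 (adjusted p = 0.283) to −1.10 (adjusted p = 0.523). Leaving out the 3 libraries lowest on the first principal component, a setting added after the data were seen, ended the calls of the antimicrobial (0.355), IL-1 and IL-36 (0.497), chemokine (0.769), stress keratin (0.497) and JAK-STAT3 lists (0.794), the last 2 with their direction turned.

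The cell cycle and epidermal differentiation lists passed upwards. Of 45 cell cycle genes 43 were positive (median 0.46, adjusted p = 1.4e-05), and of 44 epidermal differentiation genes 33 (0.55, adjusted p = 0.00196). These gave adjusted p = 0.565 and 0.579 with an estimated correlation. The thymidylate synthase gene Tyms was at 0.69 (adjusted p = 0.444) and the filaggrin family gene Flg2 at 2.50 (adjusted p = 0.167). The cell cycle call was lost without Tcn2-/- IMQ replicate 2 (adjusted p = 0.12), and the epidermal differentiation call without replicate 3 (0.216) or 4 (0.428). Barrier lipid (26 genes, 0.003, adjusted p = 0.727), basal keratinocyte (14 genes, 0.24, adjusted p = 0.0745) and hypoxia genes (27 genes, −0.06, adjusted p = 0.687) did not pass. Vitamin B12 and one-carbon (38 genes, 0.08, adjusted p = 0.0954) and type 2 cytokine genes (13 genes, −0.55, adjusted p = 0.0629) did not pass either. The vitamin B12 list included Mmaa, an enzyme of mitochondrial cobalamin handling, at 0.80 (adjusted p = 0.197).

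Skeletal muscle genes were higher in Tcn2-/- IMQ than in IMQ skin, but did not follow the genotype alone. Muscle scores were 5.99 to 7.44 in IMQ skin, 7.58 to 9.71 in Tcn2-/- IMQ skin and 8.05 to 8.18 in the wild-type controls. All 29 measured muscle genes were positive in Tcn2-/- IMQ skin (median 1.58, 27 rose when adjusted over the list alone, adjusted p = 1.56e-31, and adjusted p = 0.117 with an estimated correlation). The myosin light chain Mylpf was at 2.42 (adjusted p = 0.128). Sebaceous gland genes passed upwards (19 genes, median 1.04, 3 rose, adjusted p = 3.42e-06) and adipocyte genes downwards (23 genes, −0.61, adjusted p = 3e-04). These gave adjusted p = 0.359 and 0.46 with an estimated correlation. With the muscle score as a covariate the list calls ended for IL-23/IL-17 (adjusted p = 0.101), IL-1 and IL-36 (0.554), TNF response (0.0553) and JAK-STAT3 genes (0.968, with its direction turned). They ended too for interferon (0.622), antimicrobial (0.89), stress keratin (0.153, with its direction turned) and sebaceous gland genes (0.153). Because the score itself separates these groups, the fit cannot tell muscle content from the group difference. The call of Tcn2 ended in it too (−5.07, adjusted p = 0.109, edgeR). The calls of dendritic, neutrophil, B cell, T cell, macrophage, erythrocyte and adipocyte genes held in the 22 other settings tested at the preset correlation. The sebaceous gland call also ended without the 3 libraries lowest on the first principal component (0.769).

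A further 5 lists passed in this comparison but depended on single libraries. Hair shaft genes (36 genes, −2.84, adjusted p = 0.0217), endothelial genes (16 genes, −0.55, adjusted p = 0.021), wound matrix genes (25 genes, −0.28, adjusted p = 0.0217) and immediate early genes (20 genes, −0.44, adjusted p = 0.0188) passed downwards. Mitochondrially encoded genes passed upwards (13 genes, 0.50, adjusted p = 0.0371). All 5 missed the threshold with an estimated correlation (adjusted p = 0.673, 0.579, 0.579, 0.562 and 0.579). The hair call was lost without IMQ replicates 2 (0.993) or 5 (0.221) or Tcn2-/- IMQ replicates 1 (0.123), 3 (0.111) or 4 (0.206). The endothelial call was lost without IMQ replicates 3 (0.136), 4 (0.0652) or 5 (0.0522) or Tcn2-/- IMQ replicate 2 (0.134). The wound matrix call was lost without IMQ replicates 3 (0.23) or 5 (0.089) or Tcn2-/- IMQ replicate 2 (0.823). The immediate early call was lost without IMQ replicates 1 (0.121) or 2 (0.156) or Tcn2-/- IMQ replicate 1 (0.0701), and that list passed upwards with the muscle score as a covariate (0.0279). The mitochondrial call was lost without IMQ replicates 1 (0.0646), 2 (0.211) or 5 (0.0933) or Tcn2-/- IMQ replicates 1 (0.109) or 2 (0.402). Fibroblast genes (24 genes, 0.05, adjusted p = 0.6) and Schwann cell and melanocyte genes (15 genes, 0.34, adjusted p = 0.0954) did not pass.

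In all, 5 of 18147 genes passed between Tcn2-/- IMQ and IMQ skin, 1 that rose and 4 that fell, and 2146 had an unadjusted p below 0.05. At an adjusted p below 0.1 the counts were 5 and 19. Among these 24 the fungal pattern receptor Clec7a was at −4.96 (adjusted p = 0.053), the keratin Krt24 at 4.97 (adjusted p = 0.0644) and Il18r1 at −2.23. The libraries of both groups did not overlap for 310 genes higher and 577 lower in Tcn2-/- IMQ skin, where chance gives 144 each. Gm15446 kept its call with each of the 9 libraries left out in turn (adjusted p 2.89e-05 to 0.0387). Il1b kept it only without IMQ replicate 1 (−4.59, adjusted p = 0.013), the library with the highest Il1b value (274 CPM). It was lost at adjusted p = 0.0647, 0.0582, 0.0688 and 0.0764 without IMQ replicates 2 to 5 and at 0.113, 0.0976, 0.0974 and 0.173 without Tcn2-/- IMQ replicates 1 to 4. With the muscle score as a covariate Il1b was at −3.97 (adjusted p = 0.535, where all settings gave 1.28e-15 to 0.535). Wdfy1 lost its call without each library but IMQ replicate 1 (adjusted p over all settings 6.74e-10 to 0.322), and Gm9733 without each but IMQ replicates 1 and 3 (6.66e-06 to 0.318). The number of called genes was 5, 2, 3, 2 and 2 without IMQ replicates 1 to 5 and 1, 2, 3 and 1 without Tcn2-/- IMQ replicates 1 to 4. It was 600 with DESeq2, 42 in a fit of these groups alone, 28 with limma voom, 17 with no filter on low counts, 10 with the hair score and 30 among the libraries with Y-linked reads. With the muscle score as a covariate it was 0 (edgeR, 1012 at an unadjusted p below 0.05). Of the 32 lists 24 passed, 5 upwards and 19 downwards, and 0 passed with an estimated correlation (adjusted p from 0.117). With fry 5 passed: IL-23/IL-17, dendritic cell, B cell and muscle (0.0463 each) and erythrocyte (0.0471).

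**Figure D3:**
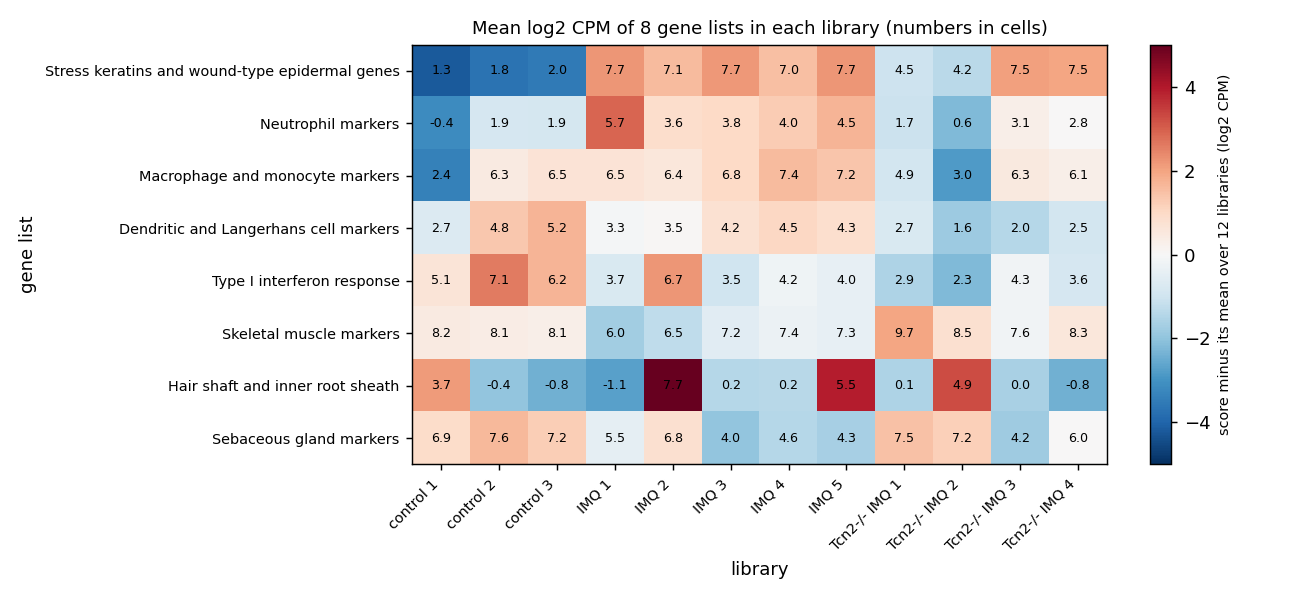
Mean log2 CPM of 8 gene lists (rows) in each of the 12 libraries (columns), printed in the cells. Colours show each score minus the mean of its list over the 12 libraries, so they do not compare levels between rows. Stress keratin scores are 6.99 to 7.70 in IMQ skin and 1.28 to 1.96 in controls, and the interferon score is 6.65 in IMQ replicate 2 against 3.48 to 4.25 in the other IMQ libraries.

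The last comparison set Tcn2-/- IMQ skin against wild-type control skin, which differ in both treatment and genotype. At the preset correlation the stress keratin and cornification lists were higher in Tcn2-/- IMQ skin, and the dendritic cell, T cell and interferon lists were lower. None of them passed with an estimated correlation (adjusted p = 0.172 for the first 4 and 0.207 for interferon). Flg rose from 55.0 ± 16.3 CPM (SD, n = 3) to 1589 ± 230 CPM (n = 4), a log2 change of 4.85 (SE 0.546, adjusted p = 0.00605, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). S100a8 rose to 366 ± 182 CPM (4.47, SE 0.766, adjusted p = 0.0224). The class II antigen-presentation gene H2-Aa fell (−4.20, SE 0.738, adjusted p = 0.0248), as did its chaperone Cd74 (−4.37, SE 0.77, adjusted p = 0.0248). The monocyte receptor Ccr2 (−4.86, SE 0.833, adjusted p = 0.0224) and Il18r1 (−4.26, SE 0.411, adjusted p = 0.00228) fell as well. H2-Aa, Cd74 and Ccr2 lost their calls without control replicates 2 (adjusted p = 0.104, 0.104 and 0.0852) or 3 (0.108 each) or Tcn2-/- IMQ replicates 3 (0.0842, 0.0846 and 0.071) or 4 (0.0889, 0.0889 and 0.0862). Sex as a covariate also ended them (0.37, 0.41 and 0.495). They were at −1.67, −1.55 and −1.16 (0.388, 0.403 and 0.425) among libraries with Y-linked reads, which hold 1 control. S100a8 lost its call without control replicates 2 (0.121) or 3 (0.0624) or Tcn2-/- IMQ replicates 3 (0.0668) or 4 (0.0633), and Flg without control replicate 3 (0.057). Among libraries with Y-linked reads both did not pass (0.17 and 0.2). Il1b was at −2.22 (SE 0.685, adjusted p = 0.156), and Stat3 at −0.15 (SE 0.251, adjusted p = 0.876).

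Of 35 stress keratin genes 21 rose (30 adjusted over the list alone), with a median of 6.16, or 5.40 with low-count members at their bounds. Krt6b, an injury-induced keratin, rose from 6.13 ± 5.11 to 3833 ± 4270 CPM (9.29, SE 1.72, adjusted p = 0.0288) and Krt16 rose by 7.21 (SE 1.21, adjusted p = 0.0224). Lce3e rose by 8.91 (SE 1.58, adjusted p = 0.0248). Of 44 epidermal differentiation genes 10 rose (32 rose and 1 fell when adjusted over the list alone). Among them were the epidermal caspase Casp14 (3.88, SE 0.52, adjusted p = 0.00841) and Rptn (7.79, SE 1.46, adjusted p = 0.0294). Of 18 antimicrobial genes 2 rose, S100a8 and Defb14 (3.54, adjusted p = 0.0248), and 1 of 18 neutrophil markers rose, Stfa2 (7.57, SE 0.972, adjusted p = 0.00789). Stfa2 hardly differed between Tcn2-/- IMQ and IMQ skin (−0.02), where the neutrophil list had a median of −1.95. Its rise may therefore not stand for neutrophils. Of 20 dendritic cell markers 9 fell (1 rose and 13 fell when adjusted over the list alone). Of 25 T cell markers 4 fell (20 adjusted over the list alone), such as the natural killer receptor Klrd1 (−3.96, SE 0.74, adjusted p = 0.0294). Of 30 interferon genes 1 fell, Irf9 (−2.07, SE 0.357, adjusted p = 0.0227), or 28 when adjusted over the list alone. The chemokines Cxcl9 (−4.97, adjusted p = 0.0267), Cxcl10 (−4.84, adjusted p = 0.0432) and Ccl1 (−4.25, adjusted p = 0.0224) fell. The macrophage elastase Mmp12 (−3.32, adjusted p = 0.0205) and the gluconeogenic enzyme Pck1 (−4.71, adjusted p = 0.0308) also fell, while the matrix protein gene Tnc rose (4.55, adjusted p = 0.0492). List tests gave adjusted p = 2.42e-41 for stress keratins, 4.55e-34 for differentiation, 8.46e-30 for interferon, 2.63e-18 for T cell and 2.34e-15 for dendritic cell genes. The same lists gave adjusted p = 0.172, 0.172, 0.207, 0.172 and 0.172 with an estimated correlation.

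Over all genes 105 rose and 133 fell in Tcn2-/- IMQ against control skin, 101 and 131 of them at least 2-fold, and 2315 had an unadjusted p below 0.05. Further leading genes were Spink7 (2 counts over the controls against 5689, ratio 2280, interval 630 to 18800) and Lce3a (2 against 3558, ratio 1420, interval 394 to 11800). The cystatin-like Cstdc6 had 3 counts against 1881 (ratio 502, interval 172 to 2440). The largest falls were in the beta-defensin Defb8 (2369 counts over the controls against 0, at least 986-fold lower), the kallikrein Klk1 (6310 against 1, ratio 7880, interval 1410 to 311000) and Chgb, a protein of secretory granules (1353 against 1, ratio 1690, interval 303 to 66800). The cytochrome Cyp4f14 fell from 77.5 ± 9.93 to 0.0741 CPM (−9.89, SE 2.16, adjusted p = 0.0492), and the protease inhibitor A2ml1 had 340 counts against 0, at least 142-fold lower. Libraries did not overlap for 848 genes higher and 1071 lower, where chance gives 518.5 each. Of the 238 genes 193, 15 and 3 remained called without control replicates 1, 2 and 3 and 169, 174, 27 and 30 without Tcn2-/- IMQ replicates 1 to 4. Il18r1 kept its call in each of these fits (adjusted p 0.00214 to 0.0154). Called genes numbered 428, 16, 3, 225, 279, 27 and 31 in these fits, 1050 with DESeq2, 2948 with limma voom, 102 in a fit of these groups alone and 27 with sex as a covariate. Among libraries with Y-linked reads, 1 control among them, they numbered 0 (edgeR, 2435 at an unadjusted p below 0.05). Of the lists 20 passed, 12 upwards and 8 downwards, 0 with an estimated correlation (adjusted p from 0.172) and 0 with fry.

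Both comparisons against control used the same 3 control libraries. In both, 79 genes rose and 32 fell, among them S100a8, Krt16, Krt6a, Flg and Defb14 upwards and Il18r1 downwards. Independent lists of these sizes would share 0.729 and 0.711. Simulated unchanged groups against the same controls called at most 1 gene, so they set no bound for the shared numbers. The controls cannot be split into parts of 2 or more, so part of the excess may come from the shared controls. Over all genes 70.3% had the same sign in both comparisons, where the simulated value was also 70.3%. Genes called between control and part of the IMQ libraries were then followed in Tcn2-/- IMQ skin against the remaining IMQ libraries. Over 10 splits of the IMQ group a median of 77.3% had the opposite sign there (range 34.9% to 87.1%), and no value without an effect was simulated for the splits. With no split it was 76.2% of 223 genes. Simulations with no Tcn2 effect gave 65.8%, but of a median of 1157 called genes, so these shares are not like for like. Over the splits, with a median of 38.5 genes, the share was 78.3% for genes that had risen and 61.2% for genes that had fallen. With no split the order was the other way (74.6% and 78.4%), and over the splits the share was 55.3% without Tcn2-/- IMQ replicate 2. With no Tcn2-/- group without IMQ, an opposite sign cannot be told from a genotype difference present before IMQ.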

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

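The tests of Il1b against cell-type lists, of the mitochondrial share, of hair follicle phase and of sex were chosen only after the result was seen. So were the settings with sex as a covariate, with only Y-linked libraries and without the libraries lowest on the first principal component.

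Within groups of 4 or 5 libraries, the gap of the highest or lowest library to its nearest neighbour was divided by the group's range, for 276 values (103 genes, 32 lists and library measures). In 21 values this ratio passed Dixon's 95% critical value for 4 or 5 libraries, which chance passes in about 1 of 20 groups. IMQ replicate 1 stood above the other IMQ libraries for Il1b (ratio 0.774, 274 CPM) and S100a8 (0.789, 5290 CPM). IMQ replicate 2 stood above them for the interferon genes Irf9 (0.755, 116 CPM), Stat2 (0.756, 137 CPM), Ifi44 (0.852, 156 CPM) and Cxcl10 (0.854, 50.3 CPM). It also stood above them for the interferon list (0.755, with a score of 6.65 against 4.25 in the next library). In the Tcn2-/- IMQ group replicate 1 was highest for Chat (0.92, 1.72 CPM), Il2rb (0.861, 2.91 CPM), Blk (0.987, 0.654 CPM) and Hbb-bs (0.922, 72.3 CPM). It was also highest for Hamp2, Klk1 and Il12b, with 1 count against 0 elsewhere (ratio 1 each), as replicate 3 was for Chgb (ratio 1). Replicate 2 was highest for Gm15446 (0.875, 1.49 CPM) and the hair shaft list (0.844, a score of 4.86). It was lowest for Clec4e (0.952, 0 CPM), Ly6c2 (0.919, 0.119 CPM) and the number of genes detected (0.904, 21417 against 23857 in the next library). Replicate 4 was lowest for Il17f (0.968, 0 CPM).

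Il1b was lower in Tcn2-/- IMQ skin by more than the mean of the macrophage or neutrophil list, but not by more than each of their members. Log2 CPM of Il1b relative to the macrophage and monocyte list differed by −3.34, relative to the neutrophil list by −2.85 and relative to the basal keratinocyte list by −5.34 (exact 2-sided permutation p = 0.00794 each, the smallest that 126 splits can give), which argues against dilution by muscle RNA, or an even fall of either list, as the whole cause. The muscle score as a covariate moved the change from −5.34 (SE 0.73) to −3.97 and ended the call (adjusted p = 0.535), in a fit where the score itself separates the groups. A loss of recruited monocytes, whose markers Ccr2 and Ly6c2 were at −4.80 and −5.75, a loss of some neutrophils (Clec4e at −4.78) and an effect of Tcn2 deficiency on Il1b itself all stay open, and no test here can tell them apart. Ly6c2 hardly differed between IMQ and control skin (0.27, adjusted p = 0.92, edgeR), and Ccr2 was lower in Tcn2-/- IMQ than in control skin as well. These values do not show a recruitment of monocytes by IMQ. Reads of the antisense transcript Il1bos may also count in part, although it was at 1.07 and 1.08 CPM in these groups.

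Control replicate 1 and Tcn2-/- IMQ replicates 1 and 2 lay low on the first principal component (−140.5, −34.1 and −98.6), and in 2 of the 3 comparisons other splits of the libraries called more genes than the labelled ones. For IMQ against control the real split called the most genes of 56 splits, 223, and the highest other called 201. A random grouping would seldom rank first, but the test cannot tell treatment from sex, which is uneven between these groups. For Tcn2-/- IMQ against IMQ 3 of 100 drawn splits called as many as the real 5. The highest other called 118, with IMQ replicates 1 and 2 and Tcn2-/- IMQ replicates 1 and 2 on a side. For Tcn2-/- IMQ against control 2 of 35 splits called as many as the real 238 and the highest other 1674 (control replicate 1 and Tcn2-/- IMQ replicates 1 and 2 on a side), so chance cannot be excluded, and counts several times the real one point to a structure of the samples. RNA quality, read as the mitochondrial share, had rho −0.462 with the component (permutation p = 0.133, adjusted over 2 relations 0.266) and r −0.828 (p = 0.00213, adjusted 0.00426), but r −0.303 and rho −0.0667 without control replicate 1 and Tcn2-/- IMQ replicate 2, so the relation rests on those libraries. Hair follicle phase had rho −0.0839 (p = 0.802) and r −0.349 (p = 0.266), with r −0.761 and rho −0.261 without IMQ replicates 2 and 5, and with so few libraries neither source, nor an unlabelled batch, can be told apart.

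Gm15446, Gm9733 and Wdfy1, which lie on chromosomes 5, 3 and 1, were called with Tcn2 and Il1b, and genes that differ between inbred strains could give such a pattern. Sex as the cause is argued against, since 3 of the 3 genes kept their call in the 9 libraries with Y-linked reads: Gm15446 at −4.13 (adjusted p = 0.0224), Gm9733 (0.0331) and Wdfy1 at 1.29 (0.0331). Within 10 Mb of Tcn2 on chromosome 11, 0 of 101 tested genes were called against 4 of 18045 elsewhere (edgeR, one-sided Fisher's exact p = 1, odds ratio up to 273), while 17.8% against 11.8% had an unadjusted p below 0.05 (one-sided p = 0.0486), so a strain segment carried with the deletion cannot be told apart from none. The genes at least 2-fold apart between all Tcn2-/- and all other libraries formed 0 pairs within 5 Mb among 11 genes, as did 73.4% of 10000 random sets (mean 0.307 pairs, permutation p = 1), which decides nothing. Strain segments elsewhere and an effect of Tcn2 deficiency on these genes stay open.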

How the results depend on the processing

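Sex as a covariate, only the 9 libraries with Y-linked reads, and leaving out the 2 or 3 libraries lowest on the first principal component were chosen only after the result was seen. Counts of called genes depended on nearly every setting. Some fits held fewer samples, and beyond that the cause was not tested for any change below. Against the 223, 5 and 238 genes called for IMQ against control, Tcn2-/- IMQ against IMQ and Tcn2-/- IMQ against control, DESeq2 called 1126, 600 and 1050. A fit of only the groups compared called 541, 42 and 102, and limma voom 3028 (1208 rose and 1820 fell), 28 and 2948. With no filter on low counts the second comparison called 17. The muscle score as a covariate gave 22 and 0 (edgeR, 1012 at an unadjusted p below 0.05) in the first pair, and the hair score 596 and 10. Sex as a covariate gave 143 for the first and 27 for the last, and the Y-linked libraries 0, 30 and 0 (4313 and 2435 unadjusted for the first and last). Leaving out 2 libraries low on the component gave 51 and 396 for the last pair, and leaving out 3 gave 631, 24 and 868. RLE and upper-quartile factors and the stricter filter kept all counts within 1.5 times, and upper-quartile factors gave 143 risen and 145 fallen genes for IMQ against control, where TMM gave 126 and 97. Leaving out 1 library gave 8 to 397, 1 to 5 and 3 to 428 genes. Of the gene lists, 23 and 24 of 32 passed, 15 of the first with the muscle score, 0 and 0 with an estimated correlation, and 18 to 24 and 21 to 24 with 1 library left out. Tcn2 in Tcn2-/- IMQ against IMQ was −5.066 with the muscle score (adjusted p = 0.109, where all settings gave 1.12e-22 to 0.197) and −4.881 to −4.48 with 1 library left out. The share of IMQ-called genes with the opposite sign, 77.3%, was 55.3% to 87.4% with 1 Tcn2-/- IMQ library left out. With no split it was 76.2% of 223 genes, against 65.8% of a median of 1157 genes in simulations with no effect. Of all other values 2473 kept direction and side of the threshold, 106 passed newly, 565 no longer passed and 28 reversed.

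Nothing in the labels says that a shared replicate number pairs samples. Of 10 pairs with the same number in different groups 5 had deviations correlated above 0.1 (range −0.531 to 0.419). The highest correlation between groups, 0.599, was between control replicate 1 and Tcn2-/- IMQ replicate 2, which have different numbers. Such correlations are thus not particular to pairs of the same number, and they cannot decide whether the samples are paired. With the replicate block the counts were 46, 0 (edgeR, 1646 at an unadjusted p below 0.05) and 20, Tcn2 was at −4.603 (adjusted p = 0.197) in Tcn2-/- IMQ against IMQ, Il6 at −0.03989 and Krt16 at −0.3101.

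Of the reversed values of single genes none passed the threshold before or after. For IMQ against control with the muscle score these were Tnf −0.1285, Cxcl1 −0.1954 and Mki67 −0.2572. Mki67 was also at −0.002923 with upper-quartile factors and −0.777 in the Y-linked libraries, and at −0.1354, −0.1143 and −0.03931 without control replicates 2 and 3 and IMQ replicate 2, within 0.7862 at the other end. Cd3e was at 0.8242 in the Y-linked libraries, which hold 1 control. For Tcn2-/- IMQ against IMQ with the muscle score Lcn2 was at 0.701, Cxcl1 at 1.576, Krt6a at 1.272 and Cd320 at 0.2579. With limma voom Cxcl1 was at 0.1873 and Krt6a at 0.0394, in the Y-linked libraries Cxcl1 at 0.1275 and Cd320 at 0.005417, and with the hair score Krt16 at −0.2144. Krt6a was at 0.2105 and 0.7468 without the 2 and 3 libraries low on the component. Leaving out IMQ replicate 1 gave Cxcl1 0.1336 and Cd320 0.02657, Tcn2-/- IMQ replicates 1 and 2 gave Krt6a 0.2076 and 0.2103, and replicates 3 and 4 gave Krt16 −0.5488 and −0.1683. The other ends with 1 library left out were Cxcl1 −1.629 (without replicate 4), Krt6a −0.9121 (replicate 3), Krt16 0.539 and Cd320 −0.3473 (replicate 2), all of the Tcn2-/- IMQ group. Depth limits the low genes, such as Il17a and Il22, at which a handful of reads decides each value.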

Other observations

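The genes below were picked after their values were seen, and the tests of other splits were fixed before their result. Across all 12 libraries, 111 genes lay at least 2-fold apart between the 3 controls and all 9 IMQ-treated libraries, 41 higher and 70 lower in control skin by library extremes. Higher in all controls were the serous gland kallikrein Klk1 (at least 75.7 CPM against at most 11.3), Chgb (24.0 against 3.70), the epidermal lipoxygenase Alox12e (214 against 65.6). So were the calcium-activated channel regulator Clca3a2 (684 against 267), the actin-severing Scin (70.7 against 31.9) and the interleukin-20 receptor chain Il20ra (14.8 against 5.31). Lower in all controls were the epidermal kallikreins Klk8 (at most 29.6 CPM against at least 124), Klk9 (12.6 against 46.5) and Klk13 (2.84 against 26.2). So were the cornification genes Cnfn (48.7 against 145) and Calm4 (400 against 1420), and the suprabasal keratin Krt1 (614 against 1690), the acute-phase gene Saa3 (3.18 against 12) and Il1f6, which encodes an IL-36 cytokine (5.28 against 22.3). As many such genes came from 2 of 220 splits of the libraries, the real one included (share 0.00909). Few groupings of these sizes gave so many, but the highest other gave 155, above the real 111. The test therefore cannot tell treatment from another structure of the samples.

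Between the 4 Tcn2-/- and all 8 other libraries 12 genes lay at least 2-fold apart, Tcn2 among them, 1 higher and 11 lower in the Tcn2-/- libraries. The gene higher was Nmrk2, a nicotinamide riboside kinase of striated muscle (at least 3.21 CPM against at most 1.58). Those lower included, at few counts, Ly6c2 (at most 0.475 CPM against at least 1.92), the chemokines Cxcl9 (1.90 against 3.90) and Ccl5 (0.772 against 1.59), and Flt3 (0.495 against 1.48). Also lower were Clec7a (1.66 against 3.85), the integrin Itgae of resident lymphocytes (3.33 against 6.85), the granzyme Gzmc (1.13 against 3.54) and the ribonuclease Ear2 (0.535 against 1.82). As many came from 5 of 495 splits, the real one included (share 0.0101). Tcn2 is low in the labelled split by construction and no count was run without it, so the test cannot exclude chance for the other genes. The highest other split gave 52, several times the real number, which points to a structure of the samples beside the genotype. Within the macrophage and monocyte list, the monocyte genes Ccr2 (−4.80, adjusted p = 0.0709) and Ly6c2 (−5.75, adjusted p = 0.126) had large falls in Tcn2-/- IMQ against IMQ skin. Ly6c2 was at 0.27 in IMQ against control skin, so it does not show a recruitment of monocytes by IMQ. Resident macrophage genes, picked by hand, had smaller changes, such as C1qa (−0.66, adjusted p = 0.793), Mrc1 (−0.36) and Cd163 (0.41). None of these genes passed over all genes. The difference between these sets of genes was not tested.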
